A study of Homo sapiens with 96 samples.

How the data were processed

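The series holds 96 RNA libraries of THP-1, a human monocytic leukaemia cell line, made with a stranded QuantSeq 3' kit, in which each read is a tag from near the 3' end of an mRNA. CRISPR guide lines carried the control guide sgRen or 1 of 2 guides per targeted gene, with 3 replicates for each guide and treatment and 32 groups in all. The lines called sgTASL here carry CXorf21, another name of TASL, or its short form CX in the labels. A first table held 30 libraries of cells without TLR9 overexpression, untreated or stimulated with R848, a small-molecule agonist of the endosomal receptors TLR7 and TLR8, at 5 µg/ml for 6 h. A second table held 66 samples of TLR9-overexpressing cells, untreated or stimulated with CpG DNA, a TLR9 ligand whose dose and time were not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

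The values in both tables are raw read counts per Ensembl gene, deposited by the authors without normalization. Per the submitters' processing notes, reads were trimmed with cutadapt 1.16 and aligned with STAR 2.5.2b to the human genome build hg38. The counter, its strand setting and the annotation were not given in the sources used here, so counts of overlapping or antisense genes, and of near-identical copies such as CCL4 and CCL4L2, are uncertain. Gene symbols matched 98.16% of the 27629 gene identifiers of the first table and 98.24% of the 27850 of the second. In the second table each of the 6 sgRen sample titles headed 2 columns, so 66 samples gave 72 columns. The paired columns were summed into 1 sample each for the main comparisons. All columns of per-sample values were used.

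Total counts ranged from 3389883 to 6119542 per library (median 4203954) in the first table and from 1568143 to 4031896 per column in the second. Genes with at least 1 count numbered 16199 to 17547 and 15429 to 17278. After the default edgeR filter on low counts, 12321 and 12667 genes were tested. Replicates were compared by a chi-square statistic per degree of freedom over genes, where 1 is sampling noise alone. Its minimum over pairs was 2.02 in the first table and 1.37 in the second, so no pair of libraries looked like the same library deposited again.

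Counts were analysed in R 4.3.3 with edgeR 4.0.16 by TMM normalization, a robust quasi-likelihood fit with 1 coefficient per guide and treatment over all libraries of a table, and quasi-likelihood F-tests with Benjamini-Hochberg adjustment at an adjusted p of 0.05. The response of a line is the log2 fold change of stimulated over untreated cells. A response difference is the response averaged over the 2 guides of a gene minus the response in sgRen cells, and an untreated difference is the mean of the guides minus sgRen without stimulus. Direct contrasts set responses of targeted lines against each other with no control library in them. CPM values are counts scaled to TMM-adjusted library sizes, as computed by the edgeR function cpm. Tests were made within a table only.

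Gene lists were tested with fry and camera from limma 3.58.1, with Benjamini-Hochberg adjustment over the lists of a comparison. Fry tests whether a list moves one way on balance. Camera compares it with the other genes and was run with a preset correlation of 0.01 and again with an estimated correlation. The lists held interferon-stimulated genes, interferon genes, cytokines, chemokines, NF-kB targets and feedback regulators, immediate-early and MAPK-response genes, endosomal TLR pathway components, lysosomal genes, cholesterol synthesis genes, cell cycle genes, monocyte and macrophage differentiation genes, unfolded protein and amino acid stress genes, and markers of other cell types. A further list held the genes induced in control cells of the other table with a log2 fold change above 1, that is 999 CpG-induced genes measured in the first table and 576 R848-induced genes measured in the second.

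The design, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined. The rule took the targeted genes with TLR7, TLR8 and TLR9, and a panel of TNF, IL1B, IL6, IL12B, CXCL8, CCL2, CCL3, CXCL10, IFIT1, IFIT2, ISG15, IFNB1, NFKBIA and TNFAIP3. For each control response it took the 10 highest and 5 lowest genes with an average log2 CPM of at least 3. For each difference it took up to 5 of the highest and 8 of the lowest genes moving the same way with each guide, for each direct contrast up to 4 each way, and up to 4 members of each list with the smallest p. Where a gene outside the rule is named, the text says so. The panel genes IL6 and, in the first table, IFNB1 fell below the filter, with 24 and 2 counts over all its libraries, and TLR8 fell below it in the second.

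The test was tried on simulated counts with known changes in 50 genes at each of 4 fold sizes. For the SLC15A4 R848 response difference (12321 genes) it recovered 26%, 70%, 92% and 100% of genes changed 1.5, 2, 4 and 8 times. Of its calls 2.70% were false. For the TASL CpG response difference (12667 genes) it recovered 24%, 64%, 90% and 96%, with 7.43% false calls. Fry and camera called 0 of 20 unchanged lists each time, but none held co-regulated genes.

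The other settings chosen then were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, a fit with only the groups compared, each guide alone, and leaving out each replicate or library in turn. Settings chosen after seeing the data concern the sgRen columns of the second table. The first and second column of each title were kept apart as separate control sets, SLC15A4 and TASL lines were compared with the first set and IRF lines with the second, and these values are called own-batch. The same was done without untreated replicate 2 of the first set, and the summed controls were also used without that column. These sets are inferred from the columns and their counts, since no label names a batch.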

Results

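RNA from THP-1 monocytic cells carrying the control guide sgRen, or guides against SLC15A4, a proton-coupled transporter of the endolysosomal membrane, or TASL, the adaptor that binds it, was profiled before and after stimulation of endosomal Toll-like receptors. Cells without TLR9 overexpression received R848, an agonist of TLR7 and TLR8, and TLR9-overexpressing cells received CpG DNA. The TLR9-overexpressing series also held lines with guides against the transcription factors IRF3, IRF5 and IRF7. Each guide and treatment had 3 libraries, and comparisons averaged the 2 guides of a gene against sgRen.

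The targeted genes were examined first. SLC15A4 mRNA fell in SLC15A4 lines without TLR9 overexpression (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, log2 fold change -1.02, SE 0.171, adjusted p = 0.00126), by more with sgSLC15A4-5 (-1.495) than with sgSLC15A4-2 (-0.54). In CPM (mean ± SD, n = 3) the untreated SLC15A4 level was 20.7 ± 2.66 in sgRen, 14.3 ± 1.77 in sgSLC15A4-2, 7.52 ± 2.43 in sgSLC15A4-5, 19.6 ± 4.75 in sgTASL-1 and 20.2 ± 2.75 in sgTASL-5 cells, and under R848 it was 17.8 ± 3.74, 14.5 ± 0.676, 7.66 ± 1.91, 18.9 ± 4.62 and 18.5 ± 1.14. SLC15A4 also fell in the TLR9-overexpressing SLC15A4 lines (log2 fold change -1.12, SE 0.168, adjusted p = 1.94e-06, own-batch -1.09). The level went from 22.7 ± 4.07 CPM in untreated sgRen cells to 13.97 ± 4.396 and 7.72 ± 1.97. The other TLR9-overexpressing lines had untreated SLC15A4 means of 22.0 to 25.9 CPM and CpG means of 15.2 to 23.7 CPM, against 11.7 ± 1.07 and 8.36 ± 1.13 in CpG-treated SLC15A4 lines and 23.2 ± 3.23 in CpG-treated sgRen cells. IRF5 mRNA fell in IRF5 lines (log2 fold change -0.72, SE 0.09, adjusted p = 1.14e-08, own-batch -0.85). It went from 89.0 ± 1.03 CPM to 55.2 ± 3.41 and 52.3 ± 4.66.

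TASL mRNA was not lowered by TASL guides in untreated cells. The log2 fold change was 0.13 (SE 0.164, adjusted p = 0.913) without TLR9 overexpression and -0.09 (SE 0.0850, adjusted p = 0.714) with it by the same edgeR test. Untreated TASL levels were 277.9 ± 37.6 CPM in sgRen, 270.6 ± 42.1 in sgTASL-1 and 339.1 ± 103.8 in sgTASL-5 cells without TLR9 overexpression, and 273.2 ± 17.1, 241.0 ± 29.2 and 273.3 ± 5.13 CPM with it. IRF3 in IRF3 lines (log2 fold change -0.44, SE 0.126, adjusted p = 0.0873, own-batch -0.45) and IRF7 in IRF7 lines (-0.40, SE 0.181, adjusted p = 0.475, own-batch -0.60) did not pass the test. IRF3 was at 31.1 ± 3.38 CPM in untreated sgRen cells and at 21.8 ± 1.81 and 24.3 ± 1.72 CPM in the IRF3 lines. IRF7 was at 10.9 ± 3.01 CPM in untreated and 157.6 ± 6.00 CPM in CpG-treated sgRen cells, and at 10.6 ± 3.40 and 6.21 ± 1.02 CPM untreated and 119.1 ± 9.98 and 97.9 ± 7.62 CPM with CpG in the IRF7 lines. A 3' tag lies away from a guide's site and can check a line's label only where the mRNA itself falls, and for TASL, IRF3 and IRF7 no fall passed the test in untreated cells.

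R848 turned on the antiviral and inflammatory programme of a monocyte in control cells. Chemokines that draw in monocytes and T cells (CCL2, CCL8, CXCL10), the pro-inflammatory cytokines TNF, IL1B and IL12B, and interferon-stimulated genes such as IFIT1, which blocks translation of viral RNA, rose together. Feedback inhibitors of NF-kB, among them NFKBIA and TNFAIP3, rose with them. The lymphoid chemoattractant IL16, the receptor tyrosine kinase KIT and the homeobox gene IRX3 fell.

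By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2214 of 12321 genes changed under R848, 1320 higher and 894 lower. CXCL10 rose from 22.3 ± 5.39 to 854.3 ± 93.7 CPM (log2 fold change 5.27, SE 0.265, adjusted p = 2.09e-13), and CCL2 (log2 fold change 5.61, SE 0.151), CCL8 (6.37, SE 0.378) and the adhesion molecule VCAM1 (5.44, SE 0.256) were among the largest. TNF rose by 3.40 (SE 0.148) and IL12B by 5.87 (SE 0.505). TLR7 (2.91, SE 0.617) and IRF7 (2.91, SE 0.158) rose too, whereas SLC15A4 (-0.23, SE 0.190, adjusted p = 0.463) and TASL (0.50, SE 0.188, adjusted p = 0.0721) did not pass. IL16 (-2.17, SE 0.197), KIT (-1.83, SE 0.281) and IRX3 (-1.80, SE 0.129) fell. IL6 was too low to test, with 24 counts over all 30 libraries. Of the fixed list of 22 interferon genes 4 were in either table, and IFNB1 could be tested only in TLR9-overexpressing cells.

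All 45 interferon-stimulated genes on the fixed list rose (fry with Benjamini-Hochberg adjustment, adjusted p = 1.53e-16, list median 2.86), for example IFIT3 (3.73), MX2 (3.28) and ISG15 (3.07). Of 14 cytokines 11 rose and 3 did not pass (13 when adjusted over the list alone), led by IL1RN (3.57). Of 17 chemokines 13 rose and 4 did not pass (13 over the list alone). Among 24 NF-kB targets and feedback regulators 21 rose and 3 did not pass (21 over the list alone, fry adjusted p = 6.31e-14), with BCL3 at 3.19, NFKBIA at 2.44 and TNFAIP3 at 2.33, which the control cells took from 41.4 ± 2.22 to 207.3 ± 10.2 CPM. Among 19 immediate-early and MAPK-response genes 14 rose and 5 did not pass (16 over the list alone), including JUNB (2.28) and the ERK phosphatase DUSP6 (1.42). Endosomal TLR pathway components split into 8 higher, 3 lower and 11 not passing of 22 (9 and 3 over the list alone), with MYD88 at 2.00 and IRF1 at 2.68. Of 999 genes that CpG induced in the other series, 710 rose, 2 fell and 287 did not pass (771 higher and 3 lower over the list alone).

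The remaining lists had fewer genes past the test under R848. Of 33 lysosomal genes 6 rose and 27 did not pass (6 over the list alone, fry adjusted p = 0.000150, adjusted p = 0.273 by camera with an estimated correlation), with SCARB2 at 0.85. Of 23 cholesterol synthesis genes 1 rose (STARD4, 0.86), 5 fell and 17 did not pass (1 and 5 over the list alone, fry adjusted p = 0.00888, adjusted p = 0.271 with an estimated correlation). Of 30 cell cycle genes 1 rose, 7 fell and 22 did not pass (1 and 7 over the list alone, fry adjusted p = 0.000168, adjusted p = 0.0874 with an estimated correlation), among them PLK1 (-0.54) and CCNA2 (-0.45). Of 25 monocyte and macrophage differentiation genes 6 rose, led by the macrophage factor MAFB (3.09), and 19 did not pass (7 higher and 1 lower over the list alone). Of 20 unfolded protein and amino acid stress genes 5 rose, 1 fell and 14 did not pass (6 and 1 over the list alone, fry adjusted p = 4.98e-07, adjusted p = 0.0984 with an estimated correlation), with PPP1R15A at 1.72. Among 7 markers of other cell types only PECAM1 rose (0.32), and 6 did not pass (1 over the list alone, fry adjusted p = 0.0405, adjusted p = 0.6 with an estimated correlation).

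Guides against SLC15A4 removed much of this response. Chemokine, cytokine and interferon-stimulated genes were induced far less, and so were NF-kB feedback genes and the MAPK-response genes JUNB, DUSP6 and EGR1. R848 lowered IL16, KIT and the chemokine receptor CXCR4 less than in control cells.

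The R848 response of SLC15A4 lines differed from that of sgRen at 914 genes, 230 higher and 684 lower (840 with sgSLC15A4-2 and 551 with sgSLC15A4-5 alone). CXCL10 reached 17.9 ± 1.5 and 37.4 ± 5.28 CPM with the 2 guides (log2 response difference -5.05, SE 0.330, edgeR with Benjamini-Hochberg adjustment, adjusted p = 1.11e-10). CCL8 (-5.53, SE 0.794), CXCL11 (-3.93, SE 0.463), CCL2 (-3.76, SE 0.196), VCAM1 (-3.48, SE 0.455), IL1RN (-3.28, SE 0.136) and TNF (-2.03, SE 0.174) fell with it. IL12B (-4.31, SE 1.10) and CXCL8 (-1.47, SE 0.426, adjusted p = 0.0356) passed with wider errors. CXCR4 (1.72, SE 0.115), KIT (1.74, SE 0.325) and IL16 (1.86, SE 0.231) were higher.

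Of the 45 interferon-stimulated genes 44 fell and 1 did not pass (45 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 2.45e-11, list median -1.85), including IFIT2 (-3.32), TNFSF10 (-3.32), IFIT1 (-2.66) and ISG15 (-2.26). Of 14 cytokines 8 fell and 6 did not pass (11 over the list alone). Of 17 chemokines 10 fell and 7 did not pass (10 over the list alone), and of 19 immediate-early and MAPK-response genes 11 fell and 8 did not pass (16 over the list alone; JUNB -1.76, DUSP6 -1.19). NF-kB targets fell at 16 of 24 genes, with 8 not passing (20 over the list alone, fry adjusted p = 1.43e-07), for example BCL3 (-1.62), TNFAIP3 (-1.35) and NFKBIA (-1.27). Among TLR pathway components 5 of 22 fell and 17 did not pass (3 higher and 6 lower over the list alone, fry adjusted p = 3.89e-06), among them IRF1 (-2.33), MYD88 (-1.39) and the TLR trafficking factor UNC93B1 (-0.86). IRF7, which is not on that list, was at -1.73. Monocyte and macrophage genes fell at 2 of 25 (MAFB -2.11; 23 not passing, 2 over the list alone, fry adjusted p = 1.15e-05). Lysosomal genes fell at 4 of 33 (29 not passing, 5 over the list alone, fry adjusted p = 0.00376, adjusted p = 0.221 with an estimated correlation), and stress genes at 2 of 20 (18 not passing, 3 over the list alone, fry adjusted p = 0.000126, adjusted p = 0.0828 with an estimated correlation; PPP1R15A -1.35). Cell cycle genes were higher at 2 of 30 (28 not passing, 4 over the list alone, fry adjusted p = 0.00234, adjusted p = 0.0537 with an estimated correlation; CDC20 0.36). Of the 999 CpG-induced genes 475 fell and 524 did not pass (1 higher and 608 lower over the list alone). Cholesterol synthesis genes (fry adjusted p = 0.524) and markers of other cell types (fry adjusted p = 0.692) did not move as lists.

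Guides against TASL gave nearly the same picture. The interferon-stimulated genes, CXCL10, CCL2, TNF and IL1RN were induced less, MAFB lost most of its induction, and R848 again lowered CXCR4, IL16 and KIT less than in control cells.

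The TASL response difference covered 765 genes, 180 higher and 585 lower (543 with sgTASL-1 and 582 with sgTASL-5 alone). CXCL10 reached 40.6 ± 2.41 and 36.2 ± 3.73 CPM (log2 response difference -4.18, SE 0.333, edgeR with Benjamini-Hochberg adjustment, adjusted p = 4.42e-09). CCL8 (-4.73, SE 0.842), VCAM1 (-3.72, SE 0.427), CCL2 (-3.41, SE 0.196), IL12B (-4.11, SE 0.993), IL1RN (-2.92, SE 0.135), CCL3 (-2.08, SE 0.447) and TNF (-1.58, SE 0.176) fell, and CXCL8 did not pass (-0.68, SE 0.432, adjusted p = 0.494). KIT (1.70), CXCR4 (1.67, SE 0.115), IL16 (1.79, SE 0.234) and the Polycomb gene CBX8 (1.45, SE 0.368) were higher.

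By list, 44 of 45 interferon-stimulated genes fell and 1 did not pass (45 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 1.27e-11, list median -1.97), for example IFIT2 (-2.78), IFIT1 (-2.35), ISG15 (-2.09) and STAT1 (-1.84). Cytokines fell at 6 of 14 (8 not passing, 9 over the list alone), chemokines at 7 of 17 (10 not passing, 8 over the list alone), and immediate-early and MAPK-response genes at 6 of 19 (13 not passing, 10 over the list alone; JUNB -1.39, DUSP6 -1.01). NF-kB targets fell at 12 of 24 (12 not passing, 17 over the list alone, fry adjusted p = 3.83e-06), with BCL3 at -1.34, TNFAIP3 at -1.05 and NFKBIA at -0.88. TLR pathway components fell at 5 of 22 (17 not passing, 2 higher and 5 lower over the list alone, fry adjusted p = 3.35e-05; IRF1 -2.07). IRF7, which is not on that list, was at -1.98. Monocyte and macrophage genes fell at 3 of 25 (22 not passing, 4 over the list alone, fry adjusted p = 0.00157, adjusted p = 0.116 with an estimated correlation; MAFB -2.14), stress genes at 1 of 20 (19 not passing, 1 over the list alone, fry adjusted p = 0.00117, adjusted p = 0.165 with an estimated correlation; PPP1R15A -1.08), and lysosomal genes at 1 of 33 (32 not passing; SCARB2 -0.78, fry adjusted p = 0.0678). PLK1 (0.44) was the 1 cell cycle gene of 30 that was higher (29 not passing, 0 over the list alone, fry adjusted p = 0.00857, adjusted p = 0.0902 with an estimated correlation). None of 7 markers of other cell types passed alone, but the list was lower as a whole (median -0.27, fry adjusted p = 0.00857, adjusted p = 0.174 with an estimated correlation). Of the 999 CpG-induced genes 409 fell and 590 did not pass (1 higher and 533 lower over the list alone), and cholesterol synthesis genes did not move (fry adjusted p = 0.196).

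**Figure D1:**
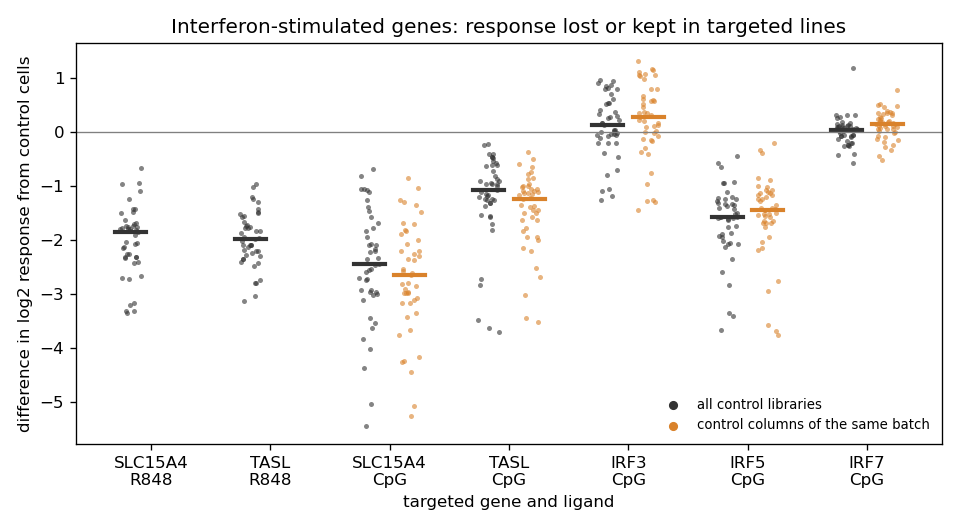
Log2 response differences of the interferon-stimulated genes for each targeted gene, under R848 and under CpG. List medians were -1.85 (SLC15A4) and -1.97 (TASL) under R848.

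Set against each other, SLC15A4 and TASL lines differed in R848 response at few or no genes. With edgeR and Benjamini-Hochberg adjustment 0 genes passed (2 with a replicate block, 10 and 0 by guide pair), with 426 at an unadjusted p under 0.05, and DESeq2 called 0. NFKBIA (-0.39, SE 0.0910, adjusted p = 0.695), TNF (-0.46, SE 0.145) and CXCL10 (-0.87, SE 0.296) did not pass. Interferon-stimulated genes showed no shift (fry adjusted p = 0.947; list mean -0.04), with 3 genes higher and 1 lower over the list alone. Cytokines (median -0.44, fry adjusted p = 0.0203, 2 lower over the list alone) and immediate-early and MAPK-response genes (median -0.29, fry adjusted p = 0.0390, 2 lower over the list alone) were lower in SLC15A4 than in TASL lines as lists. Markers of other cell types were higher (median 0.26, fry adjusted p = 0.0315), and NF-kB targets did not differ (fry adjusted p = 0.126).

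Without stimulus, guides against either gene changed few genes in cells without TLR9 overexpression when averaged. In SLC15A4 lines 12 genes passed, 3 higher and 9 lower, with 738 at an unadjusted p under 0.05 and 19 by DESeq2, and 5, all lower, without sgRen replicate 2. With sgSLC15A4-2 alone 63 passed, with the replicate number as a block 28, and the 2 guides differed from each other at 170. Besides SLC15A4 itself, 6 of the lower genes were on the interferon-stimulated list, such as MX1, a GTPase that traps viral particles (-0.90, SE 0.122, adjusted p = 0.000118 by edgeR with Benjamini-Hochberg adjustment), OAS2 (-0.72, SE 0.103) and PARP14 (-0.56). These came from sgSLC15A4-2 (MX1 -1.58, OAS2 -1.38), with values of -0.23 and -0.06 for sgSLC15A4-5. Of the 45 interferon-stimulated genes 6 fell and 39 did not pass (18 over the list alone, fry adjusted p = 0.0504). DDX49 (0.45) and IGFLR1 (0.43) were among the higher. In TASL lines 12 genes passed, 7 higher, including the proliferation marker MKI67 (0.40, SE 0.0830) and AKR1C2 (1.09, SE 0.220), and 5 lower, including SPP1 (-0.89, SE 0.185) and PLAUR (-0.50, SE 0.108). With 966 genes at an unadjusted p under 0.05, DESeq2 called 20, and edgeR called 0 with sgTASL-1 alone. These calls did not hold without single libraries, with 0 genes without any 1 of the 3 sgRen libraries, sgTASL-1 replicate 3 or sgTASL-5 replicate 1, 1 without sgTASL-5 replicate 3, 2 without sgTASL-1 replicate 1 or sgTASL-5 replicate 2, and 3 without sgTASL-1 replicate 2. Monocyte and macrophage genes were lower as a list (median -0.13, fry adjusted p = 0.000817, 0 of 25 passing and 3 over the list alone), cell cycle genes were higher (fry adjusted p = 0.0347, adjusted p = 0.0705 with an estimated correlation), cholesterol synthesis genes lower (fry adjusted p = 0.0347, adjusted p = 0.0705 with an estimated correlation) and lysosomal genes lower (fry adjusted p = 0.0137, adjusted p = 0.0521 with an estimated correlation). Interferon-stimulated genes did not differ (fry adjusted p = 0.966).

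In the TLR9-overexpressing series the 2 columns of each sgRen title were not alike. Between the first and second set of columns 1260 genes differed in untreated cells (618 higher and 642 lower in the first; 557 without untreated replicate 2 of the first set, a library apart from its set), and interferon-stimulated genes had a median difference of -0.41. By root-mean-square distance of log2 values, 11 of 12 untreated and 12 of 12 CpG libraries of SLC15A4 and TASL lines were closer to the first set, and 18 of 18 untreated and 12 of 18 CpG libraries of IRF lines to the second. The 6 CpG libraries of IRF lines closer to the first set were all of IRF5 lines. Values called own-batch take the first set for SLC15A4 and TASL lines and the second for IRF lines, as the untreated libraries lay. They were chosen after the data were seen and stand beside the main values below, and for IRF5 under CpG they do not use the nearer set. TLR9 was at 13.5 ± 4.22 CPM in untreated sgRen cells, and the untreated means of the other lines lay between 11.1 and 16.2 CPM. The share of mitochondrial reads was 7.33% to 12.5% here, against 2.09% to 2.78% in cells without TLR9 overexpression.

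CpG drove a broad response in TLR9-overexpressing control cells. Adhesion molecule VCAM1, chemokines CXCL9, CXCL10 and CXCL11, the immune checkpoint ligand CD274 and the antiviral IFIT genes rose strongly, with TNF, IL1B and IL12B. SERPINB2, an inhibitor of plasminogen activators, the receptor CXCR4 and IRX3 fell, and cell cycle genes fell as a group.

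Of 12667 genes 5987 changed, 3026 higher and 2961 lower (own-batch 5195 with the first set and 5253 with the second). VCAM1 rose by 8.22 (SE 0.289, own-batch 7.97), CXCL10 by 6.99 (SE 0.441, own-batch 6.34), CD274 by 6.71 (SE 0.365, own-batch 6.31), IFIT2 by 6.24 (SE 0.228, own-batch 6.58) and CCL2 by 6.33 (SE 0.311, own-batch 6.37). CXCL10 went from 11.3 ± 1.51 to 1441 ± 43.8 CPM. TNF rose by 4.08 (SE 0.202, edgeR with Benjamini-Hochberg adjustment, adjusted p = 2.02e-22, own-batch 3.83) and IL12B by 6.16 (SE 0.306, own-batch 5.41). IFNB1, which encodes interferon beta, rose by 3.10 (SE 0.681, adjusted p = 0.000106, own-batch 4.32). TLR7 (4.53, SE 0.594, own-batch 2.89) and IRF7 (3.86, SE 0.139, own-batch 4.17) rose, IRF5 fell (-0.43, SE 0.102, own-batch -0.33), and TLR9 did not pass (-0.17). SERPINB2 (-5.69, SE 0.336, own-batch -5.06), CXCR4 (-2.82, SE 0.147, own-batch -2.57) and IRX3 (-2.74, SE 0.09, own-batch -2.52) fell.

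All 45 interferon-stimulated genes rose (fry with Benjamini-Hochberg adjustment, adjusted p = 5.72e-33, median 3.90, own-batch 4.19 with 45 higher), as did all 16 cytokines (own-batch 15) and all 17 chemokines (own-batch 17). NF-kB targets rose at 22 of 24 (2 not passing, 22 over the list alone, own-batch 23), including TNFAIP3 (4.03, own-batch 3.88), NFKB1 (3.21, own-batch 3.02) and NFKBIA (3.04, own-batch 3.00). Immediate-early and MAPK-response genes gave 12 higher, 1 lower and 6 not passing of 19 (12 and 1 over the list alone, own-batch 11 and 1). TLR pathway components gave 12 higher, 4 lower and 6 not passing of 22 (12 and 5 over the list alone, own-batch 9 and 2), with MYD88 at 2.82. Of 31 lysosomal genes 21 rose, 3 fell and 7 did not pass (22 and 3 over the list alone, own-batch 20 and 2). Of 24 monocyte and macrophage genes 11 rose, 2 fell and 11 did not pass (11 and 2 over the list alone, own-batch 10 and 0, fry adjusted p = 2.08e-16, adjusted p = 0.0509 with an estimated correlation), with MAFB at 5.37. Cell cycle genes gave 2 higher, 18 lower and 10 not passing of 30 (2 and 18 over the list alone, own-batch 2 and 15), with CDC20 at -0.80 and PLK1 at -0.83. Cholesterol synthesis genes gave 3 higher, 10 lower and 9 not passing of 22 (3 and 11 over the list alone, own-batch 3 and 9, fry adjusted p = 3.02e-07, adjusted p = 0.135 with an estimated correlation). Of 20 stress genes 8 rose, 3 fell and 9 did not pass (8 and 3 over the list alone, own-batch 8 and 3, fry adjusted p = 6.35e-11, adjusted p = 0.337 with an estimated correlation). Among 6 markers of other cell types PECAM1 rose (0.52) and CD19 fell (-1.02), with 4 not passing and a median and mean of opposite sign (0.09 and -0.03, fry adjusted p = 0.161). Of 576 R848-induced genes 553 rose, 1 fell and 22 did not pass (554 and 1 over the list alone, own-batch 532 and 2).

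Guides against SLC15A4 lowered the interferon side of the CpG response, by more with sgSLC15A4-2. Guanylate-binding protein GBP4, the exonuclease ISG20, CXCL9, CXCL10, CXCL11, CCL2 and the IFIT genes were induced far less. TNF and its feedback inhibitor NFKBIA lost a smaller part, while TNFAIP3 and CXCL8 did not differ from control cells. The phosphatase PPM1M and the mRNA-decay factor ZFP36L1 had a higher CpG response than in control cells.

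The CpG response of SLC15A4 lines differed from sgRen at 1495 genes, 561 higher and 934 lower (1273 with sgSLC15A4-2 and 853 with sgSLC15A4-5 alone). Own-batch it was 1517 (620 higher and 897 lower), of which 1015 were shared, and 792 (223 and 569) without the odd control library, untreated replicate 2 of the first set. GBP4 fell by 5.03 (SE 0.334, edgeR with Benjamini-Hochberg adjustment, adjusted p = 1.93e-24, own-batch -5.07), ISG20 by 5.44 (SE 0.701), CXCL10 by 5.61 (SE 0.751, own-batch -4.95), CCL2 by 4.14 (SE 0.407, own-batch -4.18), IFIT1 by 4.02 (SE 0.375, own-batch -4.45) and IFIT2 by 3.83 (SE 0.433, own-batch -4.17). IFIT1 lost more with sgSLC15A4-2 (-5.43) than with sgSLC15A4-5 (-2.61). TNF fell by 1.32 (SE 0.241, adjusted p = 6.26e-05, own-batch -1.07) and NFKBIA by 0.52 (SE 0.0970, own-batch -0.48). TNFAIP3 (-0.10, SE 0.215, adjusted p = 0.848, own-batch 0.05), CXCL8 (-0.05, SE 0.459, adjusted p = 0.965), IL1B (-0.89, SE 0.548, adjusted p = 0.349) and IFNB1 (-4.11, SE 1.99, adjusted p = 0.197, own-batch -5.29) did not pass. TASL mRNA itself fell with CpG relative to control (-0.78, SE 0.125, adjusted p = 1.28e-06, own-batch -0.84), to 107.3 ± 5.43 CPM with sgSLC15A4-2 and 162.0 ± 5.65 CPM with sgSLC15A4-5, against 239.1 ± 21.3 CPM in sgRen. PPM1M (2.15, SE 0.345, own-batch 1.52) and ZFP36L1 (1.62, SE 0.237, own-batch 1.53) were higher.

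Of 45 interferon-stimulated genes 43 fell and 2 did not pass (44 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 7.21e-18, median -2.45, own-batch 44, median -2.65), with a median difference between the guides of -1.56, including CMPK2 (-2.71, own-batch -3.11), ISG15 (-2.58, own-batch -2.81) and MX2 (-2.33, own-batch -2.56). NF-kB targets fell at 7 of 24, with 17 not passing (2 higher and 9 lower over the list alone, own-batch 2 higher and 6 lower, fry adjusted p = 0.000224, adjusted p = 0.0998 with an estimated correlation; REL -0.62, CFLAR -0.62). Cytokines fell at 6 of 16 (10 not passing, 8 over the list alone, own-batch 4; IL1RN -2.74, own-batch -2.38). Chemokines gave 1 higher (CCL22, 1.37, own-batch 0.53 with adjusted p = 0.151), 8 lower and 8 not passing of 17 (1 and 10 over the list alone, own-batch 0 and 7, fry adjusted p = 0.000249, adjusted p = 0.0998 with an estimated correlation; CCL5 -0.80). Immediate-early and MAPK-response genes gave 1 higher, 7 lower and 11 not passing of 19 (2 and 8 over the list alone, own-batch 0 and 7, fry adjusted p = 0.000310, adjusted p = 0.116 with an estimated correlation; ATF3 -2.58). TLR pathway components gave 1 higher, 5 lower and 16 not passing of 22 (1 and 5 over the list alone, fry adjusted p = 2.13e-06), among them MYD88 (-2.33, own-batch -2.69) and UNC93B1 (-1.69, own-batch -1.41). IRF7, which is not on that list, was at -2.37 (own-batch -2.68).

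Cell cycle genes were higher at 4 of 30 in the same comparison (26 not passing, 4 over the list alone, own-batch 5 higher and 2 lower; fry with Benjamini-Hochberg adjustment, adjusted p = 9.32e-07; PLK1 0.54, own-batch 0.32). Cholesterol synthesis genes were higher at 3 of 22 (19 not passing, 3 over the list alone, fry adjusted p = 0.0146, adjusted p = 0.206 with an estimated correlation; NSDHL 0.82), though the own-batch median was -0.03. Lysosomal genes gave 2 higher, 4 lower and 25 not passing of 31 (fry adjusted p = 0.0438, adjusted p = 0.510 with an estimated correlation; SCARB2 -1.12), and stress genes 1 higher, 4 lower and 15 not passing of 20 (1 and 7 over the list alone, fry adjusted p = 0.000310, adjusted p = 0.206 with an estimated correlation). Monocyte and macrophage genes (2 higher, 3 lower, fry adjusted p = 0.476) and markers of other cell types (fry adjusted p = 0.123) did not move as lists. Of 576 R848-induced genes 1 was higher, 334 fell and 241 did not pass (8 and 380 over the list alone, own-batch 4 and 309).

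Guides against TASL lowered the same programme, interferon-stimulated genes by less. CXCL9, CXCL10, CXCL11, CCL2, GBP4 and the antiviral enzyme RSAD2 were induced less, and so were TNF, IL12B and IL1RN. Most NF-kB targets did not pass, and the CpG response of ZFP36L1 was again higher.

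The TASL lines differed from sgRen in their CpG response at 1052 genes, 357 higher and 695 lower (651 with sgTASL-1 and 759 with sgTASL-5 alone). Own-batch it was 1225 (520 and 705), of which 698 were shared, and 715 without the odd control library. CXCL11 fell by 4.78 (SE 0.750, own-batch -3.98), GBP4 by 3.48 (SE 0.310, own-batch -3.52), IL12B by 3.36 (SE 0.641), CCL2 by 2.72 (SE 0.402, own-batch -2.75) and RSAD2 by 2.82, and CXCL10 fell too (-3.995, SE 0.710, edgeR with Benjamini-Hochberg adjustment, adjusted p = 6.33e-05, own-batch -3.34). TNF fell by 1.19 (SE 0.239, own-batch -0.94), IL1RN by 2.61 (SE 0.207, own-batch -2.24), IFIT2 by 1.80 (SE 0.387, own-batch -2.14) and IFIT1 by 1.56 (SE 0.366, adjusted p = 0.00277, own-batch -1.99). NFKBIA fell by 0.40 (SE 0.0960, adjusted p = 0.00222), and TNFAIP3 (-0.13, SE 0.210, adjusted p = 0.816), CXCL8 (0.11) and IL1B (-0.92, adjusted p = 0.344) did not pass. IFNB1 was at -4.996 (SE 1.76, adjusted p = 0.0666), and own-batch at -6.16 (SE 2.07) it passed with adjusted p = 0.0442. TASL mRNA did not pass (-0.23, SE 0.123, adjusted p = 0.302). ZFP36L1 (1.64, SE 0.241) was higher, and SERPINB2 (2.14, SE 0.571) was higher only against the summed controls (own-batch 1.51, adjusted p = 0.238).

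Of 45 interferon-stimulated genes 35 fell and 10 did not pass (37 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 1.20e-08, median -1.08, own-batch 39, median -1.24), including TNFSF10 (-2.72), ISG15 (-1.20, own-batch -1.44) and MX2 (-1.15, own-batch -1.38). Cytokines fell at 5 of 16 (11 not passing, 9 over the list alone, own-batch 4, fry adjusted p = 2.74e-07). Chemokines gave 1 higher, 9 lower and 7 not passing of 17 (1 and 9 over the list alone, own-batch 0 and 6, fry adjusted p = 0.00244, adjusted p = 0.126 with an estimated correlation; CCL5 -0.79). NF-kB targets fell at 6 of 24 (18 not passing, 1 higher and 7 lower over the list alone, fry adjusted p = 0.00441, adjusted p = 0.126 with an estimated correlation, own-batch fry adjusted p = 0.0637), with REL at -0.62 and NFKB1 at -0.47 (own-batch -0.28). Immediate-early and MAPK-response genes fell at 5 of 19 (14 not passing, 1 higher and 5 lower over the list alone, own-batch 5, fry adjusted p = 0.00680, adjusted p = 0.150 with an estimated correlation; DUSP5 -1.94). TLR pathway components gave 1 higher, 3 lower and 18 not passing of 22, with a median of 0.01, a mean of -0.28 and a downward test (fry adjusted p = 0.00244, adjusted p = 0.132 with an estimated correlation), and IRF7 fell by 1.33 (own-batch -1.64).

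Cell cycle genes were higher at 6 of 30 in TASL lines (24 not passing, 6 over the list alone, own-batch 4 higher and 2 lower; fry with Benjamini-Hochberg adjustment, adjusted p = 4.32e-08; PLK1 0.50, AURKA 0.41), and cholesterol synthesis genes at 2 of 22 (20 not passing, fry adjusted p = 0.00680, adjusted p = 0.126 with an estimated correlation). Lysosomal genes gave 1 higher, 3 lower and 27 not passing of 31 (fry adjusted p = 0.00744, adjusted p = 0.228 with an estimated correlation; SCARB2 -1.18), and stress genes 1 higher, 3 lower and 16 not passing of 20 (1 and 5 over the list alone, fry adjusted p = 0.000556, adjusted p = 0.126 with an estimated correlation; PPP1R15A -0.57). Monocyte and macrophage genes (fry adjusted p = 0.369) and markers of other cell types (fry adjusted p = 0.830) did not move. Of 576 R848-induced genes 1 was higher, 275 fell and 300 did not pass (4 and 327 over the list alone, own-batch 3 and 243).

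Guides against IRF5 lowered much the same genes. IL12B, CXCL10, CXCL11, GBP4 and the costimulatory gene SECTM1 lost most, TNF, CCL3 and IL1RN were induced less, and the interferon-stimulated genes fell together.

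The IRF5 difference covered 971 genes, 256 higher and 715 lower (786 with sgIRF5-1 and 798 with sgIRF5-2 alone). Own-batch it covered 993 (272 and 721), of which 740 were shared. IL12B fell by 4.83 (SE 0.631, edgeR with Benjamini-Hochberg adjustment, adjusted p = 6.47e-08, own-batch -5.38), CXCL10 by 4.05 (SE 0.625, own-batch -4.58), SECTM1 by 3.79 (SE 0.390, own-batch -4.86), GBP4 by 3.67 (SE 0.274, own-batch -3.68), IL1RN by 2.65 (SE 0.201, own-batch -2.96), CCL3 by 2.62 (SE 0.554, own-batch -2.77) and CCL2 by 2.36 (SE 0.408, own-batch -2.36). TNF fell by 1.20 (SE 0.240, own-batch -1.42), and NFKBIA by 0.42 (SE 0.0960, own-batch -0.43). TNFAIP3 was at -0.55 (SE 0.202, adjusted p = 0.0891, own-batch -0.69, adjusted p = 0.0473), CXCL8 at -0.15 and IFNB1 at -2.91 (SE 1.33, adjusted p = 0.212). TASL mRNA fell relative to control as it did in SLC15A4 lines (-0.78, SE 0.124, adjusted p = 1.26e-06, own-batch -0.70), to 134.1 ± 15 and 151.2 ± 9.45 CPM.

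Of 45 interferon-stimulated genes 44 fell and 1 did not pass (45 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 1.34e-14, median -1.57, own-batch 41, median -1.44), including IFIT1 (-2.35, own-batch -2.04), IFIT2 (-2.01, own-batch -1.68) and ISG15 (-1.58, own-batch -1.44). Cytokines fell at 7 of 16 (9 not passing, 8 over the list alone, own-batch 8). Chemokines fell at 6 of 17 (11 not passing, 7 over the list alone, own-batch 1 higher and 6 lower, fry adjusted p = 0.00178, adjusted p = 0.13 with an estimated correlation). NF-kB targets fell at 6 of 24 with 1 higher (TNIP1, 0.47) and 17 not passing (1 and 10 over the list alone, own-batch 0 and 8, fry adjusted p = 0.000575, adjusted p = 0.0754 with an estimated correlation). Immediate-early and MAPK-response genes fell at 5 of 19 (14 not passing, 2 higher and 6 lower over the list alone, fry adjusted p = 0.0156, adjusted p = 0.294 with an estimated correlation; DUSP4 -1.46), with an own-batch median of 0.25. TLR pathway components fell at 3 of 22 (19 not passing, fry adjusted p = 0.00685, adjusted p = 0.294 with an estimated correlation; IRF7 -1.70, own-batch -1.49), and lysosomal genes gave 3 higher and 3 lower of 31 (fry adjusted p = 0.01, adjusted p = 0.333 with an estimated correlation; TFEB 0.94, SCARB2 -1.12). Of 30 cell cycle genes 1 was higher (29 not passing, 0 over the list alone, own-batch 2, fry adjusted p = 0.000575, adjusted p = 0.0673 with an estimated correlation). Of 576 R848-induced genes 7 were higher, 292 fell and 277 did not pass (15 and 354 over the list alone, own-batch 2 and 273). Cholesterol synthesis genes (fry adjusted p = 0.142), stress genes (0.0739), monocyte and macrophage genes (0.332) and markers of other cell types (0.620) did not move as lists.

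Guides against IRF3 changed the CpG response of few genes, in a mixed pattern. GBP4, GBP5, NFKBIA and TNFAIP3 were induced less, while antiviral OAS2, IFITM1 and STAT1 were induced more from lower untreated levels. With edgeR and Benjamini-Hochberg adjustment 38 genes passed, 6 higher and 32 lower (62 with sgIRF3-1 and 6 with sgIRF3-2 alone), with 915 at an unadjusted p under 0.05 and 53 by DESeq2. Own-batch 115 passed (29 and 86), of which 29 were shared. GBP4 fell by 1.26 (SE 0.280, adjusted p = 0.0127, own-batch -1.27), GBP5 by 1.19 (own-batch -1.28), NFKBIA by 0.48 (SE 0.0970, adjusted p = 0.00387, own-batch -0.49) and TNFAIP3 by 0.88 (SE 0.204, adjusted p = 0.0292, own-batch -1.02), the last with -1.44 for sgIRF3-1 and -0.33 for sgIRF3-2. OAS2 (0.95, SE 0.204, own-batch 1.04), IFITM1 (0.82, SE 0.149, own-batch 1.06), REC8 (1.11, SE 0.272, own-batch 1.19) and STAT1 (0.53, SE 0.111, own-batch 0.58) were higher. CXCL10 (-1.30, SE 0.583, adjusted p = 0.622), TNF (-0.21, SE 0.238, adjusted p = 0.927) and IFNB1 (1.81, SE 1.26, adjusted p = 0.839) did not pass. Interferon-stimulated genes gave 3 higher, 1 lower and 41 not passing of 45 (13 and 3 over the list alone, fry adjusted p = 0.403, own-batch 10 and 1). NF-kB targets fell at 3 of 24 (21 not passing, 6 over the list alone, fry adjusted p = 0.0335, own-batch 4), and R848-induced genes gave 4 higher, 16 lower and 556 not passing of 576 (15 and 49 over the list alone, own-batch 12 and 27). Leaving out 1 library gave 21 genes without sgRen untreated replicate 3, 22 without sgRen CpG replicate 1 and 24 without sgRen untreated replicate 1 or replicate 2.

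With guides against IRF7 the CpG response was close to that of control cells. The edgeR test with Benjamini-Hochberg adjustment passed 2 genes, with 695 at an unadjusted p under 0.05 and 2 by DESeq2. They were the chemokine CCL22 (-0.98, own-batch 0.23 and so of the other sign) and the lipoprotein receptor LRP8 (-0.54, SE 0.105, adjusted p = 0.00879, own-batch -0.59, SE 0.113, adjusted p = 0.0140). LRP8, and C3AR1 below, lie outside the naming rule and were chosen after their values were seen. Without sgRen CpG replicate 2 or sgRen untreated replicate 1 the count was 0, and it was 1 without sgRen CpG replicate 3, sgRen untreated replicate 2 or replicate 3, or sgIRF7-1 untreated replicate 2. TNF (0.78, SE 0.246, adjusted p = 0.810), CXCL10 (0.88, SE 0.659, adjusted p = 0.947), ISG15 (0.33, SE 0.180, adjusted p = 0.930) and IFNB1 (0.57, SE 1.11, adjusted p = 0.979) did not pass. No list moved, with fry adjusted p = 0.922 for interferon-stimulated genes, 0.309 for NF-kB targets, 0.241 for cytokines and 0.462 for R848-induced genes.

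**Figure D2:**
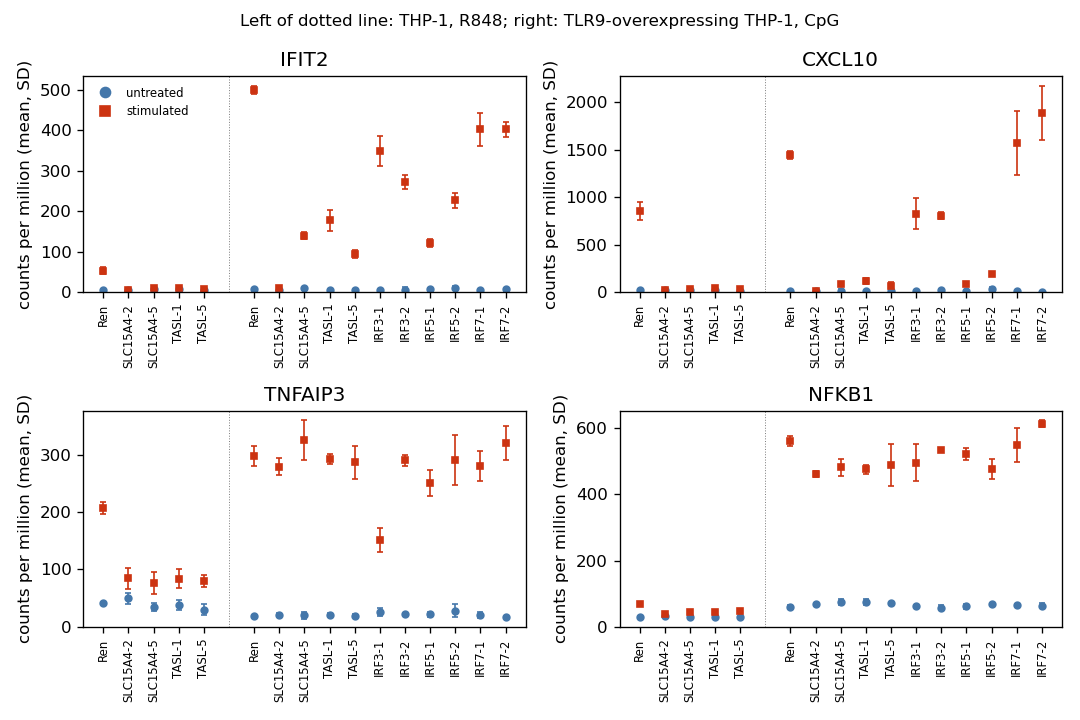
CPM (mean ± SD, n = 3) of IFIT2, CXCL10, TNFAIP3 and NFKB1 in each line with and without stimulus. With CpG, IFIT2 stood at 498.6 ± 9.67 CPM in sgRen cells and at 10.7 ± 2.70 and 139.2 ± 8.42 CPM in SLC15A4 lines.

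Direct contrasts of the CpG responses, which hold no control library, separated SLC15A4 from TASL lines at 106 genes, 7 higher and 99 lower (134 for sgSLC15A4-2 minus sgTASL-1 and 1, the complement receptor gene C3AR1 at -2.13, for sgSLC15A4-5 minus sgTASL-5, own-batch 101, with 100 shared). Interferon-stimulated genes made up much of it, with 34 of 45 lower and 11 not passing (40 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 3.72e-10, median -1.31, own-batch 34 and -1.31). CMPK2, a mitochondrial nucleotide kinase, was at -1.61 (SE 0.149, edgeR adjusted p = 1.38e-14; -3.22 and 0.00 by guide pair), IFIT3 at -2.31 (SE 0.279; -3.55 and -1.07), IFIT1 at -2.46 (SE 0.364; -4.24 and -0.68), MX2 at -1.19 (SE 0.136) and CCL2 at -1.43 (SE 0.359, adjusted p = 0.0330). TNF (-0.13, SE 0.207, adjusted p = 0.934), NFKBIA (-0.13, SE 0.0800, adjusted p = 0.750) and CXCL10 (-1.61, SE 0.681, adjusted p = 0.486) did not pass. Neither NF-kB targets (fry adjusted p = 0.408) nor cytokines (0.954) nor chemokines (0.372) moved as lists. TLR pathway components fell at 2 of 22 (20 not passing, 4 over the list alone, fry adjusted p = 0.0184, adjusted p = 0.105 with an estimated correlation; UNC93B1 -0.90). Of 576 R848-induced genes 89 fell (487 not passing, 2 higher and 143 lower over the list alone, own-batch 88). TASL mRNA was lower in SLC15A4 than in TASL lines (-0.55, SE 0.108, adjusted p = 0.000654).

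Against IRF5 lines, SLC15A4 lines differed at 381 genes, 167 higher and 214 lower (301 and 25 by guide pair). With each line set against its own-batch controls they differed at 170 (83 and 87), of which 55 were shared, and at 47 without the odd control library. Interferon-stimulated genes fell at 29 of 45 (16 not passing, 37 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 4.99e-06, median -0.74, own-batch 18, median -1.17), including CMPK2 (-1.22, SE 0.142, own-batch -1.88), the RNA sensors RIGI (-1.37, own-batch -1.52) and IFIH1 (-1.13, own-batch -1.54), and IFIT1 (-1.67, SE 0.324, own-batch -2.41). CCN2 (1.78, own-batch -0.17), CCL22 (1.49, own-batch -0.56) and PALLD (1.15, own-batch -0.23) took the other sign own-batch. TASL lines differed from IRF5 lines at 119 genes, 82 higher and 37 lower (89 and 25 by guide pair), and own-batch at 179 (118 and 61), of which 10 were shared, and at 28 without the odd library. Interferon-stimulated genes were higher at 14 of 45 in the direct contrast (31 not passing, 25 over the list alone, fry adjusted p = 0.00566, median 0.39), and own-batch at 0 (fry adjusted p = 0.807, median 0.05). PARP14 (0.63, SE 0.115, own-batch 0.63 with adjusted p = 0.0783) and OAS2 (0.89, own-batch 0.65 with adjusted p = 0.242) passed in the direct contrast and not own-batch, and the count was 76 without sgIRF5-2 untreated replicate 3. NF-kB targets did not differ in either contrast (fry adjusted p = 0.801 and 0.760).

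Untreated TLR9-overexpressing lines differed from control as well, but much of that depended on which control columns were used. In SLC15A4 lines 594 genes passed, 199 higher and 395 lower, but own-batch 305 (136 and 169), and 11 when untreated replicate 2 of the first control set was also left out. IFI27, an interferon-induced mitochondrial protein, was at -1.91 (SE 0.193, own-batch -0.28, adjusted p = 0.656) and the neuronal pentraxin gene NPTX1 at 1.13 (SE 0.179, edgeR with Benjamini-Hochberg adjustment, adjusted p = 5.57e-06, own-batch 1.36). Galectin LGALS9 was at -0.41 (SE 0.0700, own-batch -0.39 with adjusted p = 0.00224). Cholesterol synthesis genes fell at 7 of 22 (15 not passing, 11 over the list alone, fry adjusted p = 3.50e-10, own-batch 0, fry adjusted p = 0.000490), with ACAT2 at -0.68 (own-batch -0.24), and 5 of 45 interferon-stimulated genes fell (40 not passing, 6 over the list alone, fry adjusted p = 0.184, own-batch 1). The count was 292 without sgRen untreated replicate 2 and 392 without replicate 3.

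In TASL lines 272 genes passed untreated, 92 higher and 180 lower, own-batch 221 (105 and 116), and 16 without the odd control library. LGALS9 (-0.44, own-batch -0.42 with adjusted p = 0.000801) and the sterol gene SQLE (-0.46, SE 0.0800, own-batch -0.36 with adjusted p = 0.0217) also passed own-batch, and IFI27 (-2.01, SE 0.186, own-batch -0.39 with adjusted p = 0.525) did not. Interferon-stimulated genes fell at 12 of 45 (33 not passing, 20 over the list alone; fry with Benjamini-Hochberg adjustment, adjusted p = 0.00164, own-batch 1, fry adjusted p = 0.693), and cholesterol synthesis genes at 2 of 22 (20 not passing, 7 over the list alone, fry adjusted p = 1.09e-07, own-batch 1, fry adjusted p = 0.0830). The count fell to 146 without sgRen untreated replicate 3, 151 without replicate 1 and 156 without replicate 2. The myeloid protease PRTN3, a marker of other cell types, was higher in SLC15A4 lines (0.30) and TASL lines (0.33).

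IRF3 lines had lower interferon-stimulated genes before any stimulus against either control. Of 92 genes, 21 higher and 71 lower (own-batch 53, 2 and 51), IFI27 (-2.29, SE 0.189, edgeR with Benjamini-Hochberg adjustment, adjusted p = 1.90e-17, own-batch -2.90), MX1 (-1.73, SE 0.215, own-batch -1.94), IFI6 (-1.68, SE 0.190, own-batch -2.12), IFITM1 (-1.48, SE 0.121, own-batch -1.72) and STAT1 (-0.80, SE 0.0810, own-batch -0.96) were among the lowest. On the list 24 of 45 fell and 21 did not pass (35 over the list alone, fry adjusted p = 2.05e-08, median -0.77, own-batch 26, median -0.94). Without sgRen untreated replicate 2 the count was 52. IRF5 lines differed at 53 genes, 30 higher and 23 lower, and own-batch at 1, which was IRF5. Interferon-stimulated genes were higher at 7 of 45 there (38 not passing, 22 over the list alone, fry adjusted p = 0.00215, own-batch 0, fry adjusted p = 0.300), and leaving out sgRen untreated replicate 2 gave 20 genes and leaving out sgIRF5-1 untreated replicate 2 gave 30. IRF7 lines differed at 49 genes, 21 higher and 28 lower, and own-batch at 10 (4 and 6), and the count was 20 without sgRen untreated replicate 2. The growth-response factor EGR1 was lower in IRF7 lines (-1.08, SE 0.110, own-batch -0.74 with adjusted p = 0.000263), with 2 of 19 immediate-early genes (17 not passing, 4 over the list alone, fry adjusted p = 0.00765, own-batch 1), and interferon-stimulated genes did not differ (fry adjusted p = 0.812).

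SLC15A4, TASL and IRF5 guides lowered many of the same responses. With SLC15A4 guides 438 genes fell in both the R848 and CpG response differences, where 51.8 would be shared by independent draws, and 68 were higher in both (10.5), with 5 opposite (Pearson 0.579, Spearman 0.374). With TASL guides 338 fell in both (33.3) and 34 were higher in both (5.17; Pearson 0.502, Spearman 0.345, or 0.120 with no filter on low counts). The 338 became 211, 200 and 236 without replicates 1, 2 and 3. TASL guides under R848 and IRF5 guides under CpG shared 342 lower genes (34.2). With IRF3 guides 22 of 32 lower genes were shared (1.57), and IRF7 guides lowered too few to compare. Within the CpG series, SLC15A4 and IRF5 lines shared 583 lower genes, and 450 (51.1) own-batch, where no library is shared. TASL and IRF5 lines shared 515, and 357 (40.2) own-batch. SLC15A4 and TASL lines shared 602, and 443 or 410 with separate controls. In control cells 1122 genes rose (303.2) and 689 fell (212.9) with both ligands, and 23 went opposite ways. Independent draws therefore set a low bar for shared losses.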

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

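The guide and control-set differences below, and the tests of the 3 patterns weighed here except the comparisons with cells without TLR9 overexpression, were chosen after the results were seen. Counts are genes passing the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, and groups of 3 libraries were not tested for outliers.

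CpG responses differed at 106 genes for SLC15A4 minus TASL (134 and 1 by guide pair), 381 for SLC15A4 minus IRF5 (55 shared own-batch) and 119 for TASL minus IRF5 (10 shared). The 2 SLC15A4 guides differed at 170 genes in untreated cells without TLR9 overexpression, where interferon-stimulated genes had a median of -0.70 (sgSLC15A4-2 minus sgSLC15A4-5), and at 12 in the R848 response. In TLR9-overexpressing cells they differed at 11 genes untreated and at 74 in the CpG response, where the list median was -1.56. TASL guides differed at 153 genes in untreated TLR9-overexpressing cells. IRF3 guides differed at 31 untreated and 63 in the response, IRF5 guides at 1 and 33, and IRF7 guides at 5 and 3. The 2 sgRen sets differed at 1260 genes untreated and at 381 in the CpG response.

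Interferon-stimulated genes lost more of the CpG response with SLC15A4 than with TASL guides. If this came from the stronger line sgSLC15A4-2 alone, where 37 of 45 genes were lower than the mean of the TASL guides (median -2.16), sgSLC15A4-5 would match TASL. Its median was -0.52 and fry called the list lower, but edgeR called 0 of the 45 genes, so that reading was not excluded. Under R848 the median difference was 0.00076 (fry with Benjamini-Hochberg adjustment, adjusted p = 0.947), with 29.7% of the response kept in SLC15A4 and 28.7% in TASL lines. For this list, that argues against a larger loss under both ligands, though less was left to lose than under CpG. Whether the loss is TLR9-specific stays open.

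Untreated TLR9-overexpressing lines differed from the summed controls at 594 genes with SLC15A4 guides and 272 with TASL guides. With own-batch controls 305 and 221 passed, and without the odd library too 11 and 16, of which 6 and 5 were among the first calls. The summed controls without that library raised both counts, to 466 for TASL, so the odd library alone was not the source. The calls depend on the controls used, and the parts of another batch, of the odd library and of fewer libraries could not be told apart. If loss of the targeted gene were the source, the called genes would fall on the same side in cells without TLR9 overexpression. For SLC15A4 60.03% of 583 did and for TASL 51.9% of 266, each against 52.0% of all genes. A part could thus come from loss of SLC15A4. For TASL no shared effect showed, but one only in TLR9-overexpressing cells was not excluded.

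Interferon-stimulated genes were lower in untreated IRF3 lines. Against the mean of the IRF5 and IRF7 lines, which share their batch, the median was -0.92 (34 of 45 lower by edgeR), so control columns of another batch were excluded as the source. The weaker guide had a median of -0.89 and the other -0.98 against the second control set, which excludes 1 IRF3 guide line. A role of IRF3 in their resting level is likely on these tests, as a hypothesis, though IRF3 mRNA itself did not pass.

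Other splits of the libraries, with both guides pooled as 1 group, were counted for each comparison. For the control responses 10 splits are too few for a share under 0.05 (R848 2273 genes, highest other 0, count 1; CpG 5688, 0 and 1). The share was under 0.05 for the CpG response difference of TASL (830 genes, highest other 2, 1 of 40 splits as large). It was so for IRF5 (876, 5, 1) and SLC15A4 minus IRF5 (190, 1, 1). So it was for untreated TLR9-overexpressing SLC15A4 (318, 7, 1 of 84), TASL (26, 45, 2) and IRF3 lines (32, 321, 3). IRF5 (30, 343, 4) and IRF7 lines (44, 69, 2) were alike. The share was not under 0.05 for the R848 response differences of SLC15A4 (791, 1026, 2 of 40) and TASL (736, 1342, 2 of 40) and the CpG response difference of SLC15A4 (1171, 1791, 3 of 40). There the splits above the real count exchanged only untreated control libraries, so they still held the loss of response. No other drawn split gave more than 1 gene, so those shares are no sign of chance. Chance was not excluded for the CpG response difference of IRF3 (7, 48, 4 of 40) or for TASL minus IRF5 (53, 436, 2 of 40). Where the real pooled count was 0 every split is as large, and the splits say nothing about chance. This was so for the CpG response difference of IRF7 (highest other 9) and SLC15A4 minus TASL under R848 (1) and CpG (2). It was so for untreated SLC15A4 (82) and TASL lines (62) without TLR9 overexpression. Splits mix lines and control sets, so they exclude neither as the source. With guides fitted apart, SLC15A4 minus TASL under CpG gave 106 genes by edgeR and 114 by DESeq2.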

How the results depend on the processing

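The own-batch alternatives, and those without the odd control library, were chosen after the results were seen, and the others were planned. The count of each comparison was run with DESeq2 size factors, without the filter on low counts, with the replicate number as a block, with the DESeq2 Wald test, without each library in turn and, where targeted lines enter, with each guide alone. List tests were not run with the Wald test, and of the overlaps only that of TASL guides under both ligands (338) was rerun without a replicate number, giving 200 to 236. Where a call or count changed, the cause was not tested.

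Counts that stayed within 1.5 times the main one under every alternative run were those of the control responses, of the TASL response difference under R848 and of the IRF5 response difference under CpG. DESeq2 size factors changed no count by more than that. Outside that range under R848 were the SLC15A4 response difference with sgSLC15A4-5 alone (551 against 914), and the SLC15A4 minus TASL contrast (0 by edgeR, 426 at an unadjusted p under 0.05 and 0 by DESeq2), which gave 4 genes with no filter, 2 with the block and 10 with the lower-numbered guides. Untreated SLC15A4 lines (12) gave 22 with no filter, 28 with the block, 19 by DESeq2, 7 with only the groups compared and 63 with sgSLC15A4-2. Untreated TASL lines (12, with 966 at an unadjusted p under 0.05) gave 24, 21, 20 and 0 in the same order and 0 with sgTASL-1.

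In TLR9-overexpressing cells the CpG response difference of SLC15A4 (1495) gave 792 own-batch without the odd library and 853 with sgSLC15A4-5, and that of TASL (1052) gave 651 with sgTASL-1. IRF3 (38) gave 115 own-batch, 170 own-batch without the odd library, 62 with sgIRF3-1 and 6 with sgIRF3-2. IRF7 (2) gave 1 with no filter, 1 own-batch, 7 own-batch without the odd library, 1 with only the groups compared, 1 with sgIRF7-1 and 11 with sgIRF7-2. SLC15A4 minus TASL (106) gave 1 with the higher-numbered guides. SLC15A4 minus IRF5 (381) gave 170 own-batch, 47 without the odd library and 25 with the higher-numbered guides, and TASL minus IRF5 (119) gave 179, 28 and 25.

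Untreated TLR9-overexpressing SLC15A4 lines (594) gave 305 own-batch, 11 own-batch without the odd library, 359 with only the groups compared, 305 with sgSLC15A4-2 and 346 with sgSLC15A4-5. TASL lines (272) gave 16 own-batch without the odd library, 466 with the summed controls without it, 95 with only the groups compared and 173 with sgTASL-1. IRF3 lines (92) gave 53 own-batch, 51 with the summed controls without the odd library, 51 with only the groups compared and 42 with sgIRF3-1. IRF5 lines (53) gave 1 own-batch, 3 own-batch without the odd library, 19 with the summed controls without it and 33 with sgIRF5-2. IRF7 lines (49) gave 86 with no filter, 90 by DESeq2, 10 own-batch, 23 with the summed controls without the odd library and 19 with sgIRF7-1. The DESeq2 Wald test moved the share of lower genes in untreated cells without TLR9 overexpression from 75.0% to 63.2% for SLC15A4 and from 41.7% to 55% for TASL, and the block moved it to 60.7% and 57.1%. Without the filter it rose to 87.0% for untreated TLR9-overexpressing SLC15A4 lines and 84.9% for TASL lines (from 66.5% and 66.2%), and SLC15A4 minus IRF5 went from 167 higher and 214 lower to 207 and 191.

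Without 1 library at a time, the R848 counts ranged from 1786 to 1947 (control), 749 to 916 (SLC15A4), 625 to 809 (TASL) and 0 to 1 (SLC15A4 minus TASL, 1 without sgTASL-1 untreated replicate 3). Untreated SLC15A4 lines gave 5 to 17 and untreated TASL lines 0 to 3. CpG counts ranged from 5357 to 5570 (control), 1102 to 1551 (SLC15A4), 802 to 1030 (TASL), 21 to 42 (IRF3), 821 to 974 (IRF5), 0 to 2 (IRF7), 91 to 115 (SLC15A4 minus TASL), 282 to 406 (SLC15A4 minus IRF5) and 76 to 124 (TASL minus IRF5, 76 without sgIRF5-2 untreated replicate 3). Untreated TLR9-overexpressing lines ranged from 292 to 552 (SLC15A4), 146 to 281 (TASL), 52 to 97 (IRF3), 20 to 49 (IRF5) and 20 to 51 (IRF7). The report names the libraries behind the low ends for IRF3, IRF7 and the untreated lines.

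Of 628 passing values of named genes 621 still passed with DESeq2 size factors, 602 with the DESeq2 Wald test, 598 with no filter and 624 with the block, and 465, 450 and 480 without replicates 1, 2 and 3 of all groups. Of the 447 in TLR9-overexpressing cells, 283 kept their side own-batch, 152 no longer passed and 12 changed sign. Without the odd library too, 252 kept it, 180 did not pass and 15 changed sign, and with the summed controls without it 410 kept it. Fry called 112 lists in all, 116 with the block, 98 own-batch and 88 to 101 without a replicate number. Of the targeted mRNAs 3 passed, and 2 to 3 without a replicate number.

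Signs changed own-batch for CCL22 (IRF3 0.30, IRF7 0.23, SLC15A4 minus IRF5 -0.56, TASL minus IRF5 -0.62), CCN2 (-0.17 and -0.008 in those contrasts), DUSP2 (-0.67 and -0.66), OAS1 (TASL minus IRF5 -0.29), PALLD (SLC15A4 minus IRF5 -0.23, untreated SLC15A4 lines 0.16) and ATP6V1B2 (untreated SLC15A4 lines 0.037). Without the odd library too they changed for CCL22 (0.30, 0.23, -0.75 and -0.81), DUSP2 (-0.64 and -0.63), OAS1 (-0.12) and PALLD (-0.014) in the same comparisons. They also changed there for PPM1M (CpG TASL -0.28) and, in untreated lines, for DNAJC3 (SLC15A4 -0.022), EBP (SLC15A4 0.027), GOLGA8N (TASL -0.067), IFI6 (TASL 0.11) and IFITM3 (SLC15A4 0.15, TASL 0.018).

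Replicate numbers were not taken as pairs, though in cells without TLR9 overexpression libraries of the same number shared some variation (median residual correlation 0.107, against -0.0503 for other numbers). Residuals correlated above 0.1 in 72 of 135 pairs of the same number in cells without TLR9 overexpression and in 54 of 693 with it, and 20 of 30 and 27 of 66 libraries were closest to their own number. Counts with the block were 2512, 1098 and 912 for the R848 control, SLC15A4 and TASL comparisons. At a median of 4203954 counts per library, IL6 (24 counts) and TLR9 in cells without its overexpression (62 counts) were not measurable, and the self-test recovered 26% of genes changed 1.5 times.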

Other observations

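The hypothesis and its test here were chosen after the results were seen. Beyond the comparisons above, 3 genes that R848 lowered in control cells, picked after their values were seen, were lowered less in targeted lines. They were IL16, KIT and CXCR4. Their log2 response differences were 1.86, 1.74 and 1.72 in SLC15A4 lines and 1.79, 1.70 and 1.67 in TASL lines. In control cells R848 lowered IL16 by 2.17, KIT by 1.83 and CXCR4 by 1.71 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 6.12e-12 for IL16). In IRF3 lines IFITM1, OAS2 and STAT1 started lower (-1.48, -1.47 and -0.80) and rose more with CpG (0.82, 0.95 and 0.53), so their CpG-treated levels lay closer to control than their untreated ones.

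The share of the log2 response to a ligand that a line kept, as a median over induced genes, was set side by side for 2 lists. Under CpG, NF-kB targets kept 89.8% with SLC15A4, 89.98% with TASL, 87.4% with IRF5, 90.5% with IRF3 and 107.4% with IRF7 guides, interferon-stimulated genes 37.4%, 71.1%, 58.5%, 103.6% and 101.0%, and all induced genes 64.4%, 71.1%, 70.1%, 88.8% and 100.7%. Under R848, NF-kB targets kept 45.8% with SLC15A4 and 57.1% with TASL guides, interferon-stimulated genes 29.7% and 28.7%, and all induced genes 22.8% and 28.5%.

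A hypothesis is that NF-kB targets may depend less than interferon-stimulated genes on SLC15A4, TASL and IRF5 under CpG. If so, NF-kB targets would keep more of their response, and they kept 52.4 points more with SLC15A4, 18.9 with TASL and 28.97 with IRF5 guides (p = 1e-05 each by permutation of genes, the smallest possible with 100000 draws). Genes are not independent, and IRF7 lines, with 2 genes changed, also gave p = 0.00094, so this permutation p runs too low. The list counts were known before, so the test adds no independent support. Interferon-stimulated genes kept less than induced genes in general with SLC15A4 and IRF5 guides under CpG, but not with TASL guides under CpG or with either gene under R848.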
